A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

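RNA of a wild type and an hfq mutant of the cyanobacterium Synechocystis was compared on 8 two-colour Agilent arrays of 1 slide (array design 016989). Per the labels' protocols, total RNA was reverse transcribed, labelled with Cy3 or Cy5 through amino allyl groups and hybridised with the dyes exchanged. Scans were quantified by the authors with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited intensity values are linear mean signals per spot and median local backgrounds in each channel, not background-corrected, per the file headers. The deposited log10 ratios are Cy5 over Cy3 from signals that the software had background-subtracted, detrended and dye-normalised, per the file headers. A deposited table of log10 values for the series does not state its direction. It was compared with the log10 ratio of each array, and equalled it on arrays with wt in Cy3 and its negative on arrays with hfq in Cy3, within 0.00497. Its column medians were 0.00094, -0.0145, 0.00275 and -0.00316 on the former arrays and -0.00228, -0.0213, 0.00317 and -0.00604 on the latter, so it runs as hfq over wt by the labels and is centred near 0. It does not settle which RNA was in which dye.

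From the scanner values, background was corrected by normexp with an offset of 50 on mean signals and median local backgrounds, and each array was normalised by loess. The 536 control spots per array and outlier spots had weight 0 in loess and were then left out; outlier spots made up 2.89% to 12.2% of spots. Ratios were turned to hfq minus wt by the dye labels, in which title, source name and dye agree on all arrays. Spots of a probe were averaged, then the probes of a gene. A probe was to be kept if well above background in at least 6 of the 8 readings of at least 1 strain, and the filter removed 0 probes. Of the genes, 61 had 1 probe, 1611 had 2, 1560 had 3 and 32 had 4; 74 genes share a probe sequence with another gene, and 1 gene without enough values was left out. As the 4 RNA pairs share preparations, least squares with a dye term reduced the 8 arrays to 1 log2 value for each of 4 preparations.

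Strains were compared on 2 against 2 preparation values with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The fit had 2 residual and 5.88 total degrees of freedom. Every adjusted p for a gene is from limma, and every standard error is the moderated one. The 10/07 and 04/07 preparations were compared with strain as a covariate and 1 residual degree of freedom. That fit had 17.4 total degrees of freedom, so its standard errors rest mostly on spread pooled over genes. All 8 arrays were on 1 slide, so no slide could be used as a block. Gene lists were compared with the other genes by camera in limma with a preset correlation of 0.01, and also with an estimated correlation. Camera with the estimated correlation rests on the 2 residual degrees of freedom, so few lists could pass it. A list that does not pass it is not shown to be unshifted. As a test of another kind, fry asked whether the genes of a list move, on balance, one way, without comparing them with other genes. All had Benjamini-Hochberg adjustment over the 21 lists of at least 3 measured genes.

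The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule names ssr3341, the 7 motility loci, and the 10 largest differences in each direction among genes past the threshold with all 4 pair ratios of that sign. Where fewer passed it names them all, and where none passed the 5 genes of smallest p with all signs alike. It also takes up to 4 members of smallest p from each list described. Other genes are named as chosen after their values were seen. The 29 lists were motility operons, type IV pilus assembly, pilins, chemotaxis-like clusters, cAMP signalling, RNA chaperones and RNases, sigma factors, photosystem I, photosystem II, phycobilisome, phycobilisome degradation, cytochrome b6f and electron carriers, ATP synthase, chlorophyll biosynthesis, ribosomal proteins, carbon concentration and fixation, nitrogen assimilation, phosphate response, iron response, heat shock and chaperones, high light and photosystem repair, hydrogenase, CRISPR-associated genes, the plasmids pSYSM, pSYSX, pSYSA and pSYSG, transposases and noncoding RNAs. The last 7 of these had 0 genes that could be assigned on the array and are not analysed here. The arrays give locus tags without names or coordinates, and 0 of the 3263 tags were found in the reference table used, so lists rest on general knowledge of locus tags.

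The fit was tested on simulated data made from the 3263 genes and the measured spread between preparations, with 50 genes changed at each size. With independent preparations it recovered 8% of genes changed by 1 log2 unit, 66% at 2, 94% at 4 and 94% at 5, and called 6 unchanged genes. With preparations that share most of their deviation through the label it recovered 8%, 78%, 84% and 92%, and called 0 unchanged genes. A fit with the preparation label as a block recovered 56%, 100%, 98% and 100% of these, with 7 unchanged genes called, and 0%, 18%, 82% and 94% with independent preparations, with 1 called. In both cases the fit used therefore missed most changes of 1 log2 unit.

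Alternatives were no background correction, Agilent's processed log10 ratios, median centring, the deposited table, no filter on dim probes, the median of the probes, a fit per probe, and a 2-fold minimum. Other alternatives took the 4 pair ratios or 8 arrays as the unit of replication, the RNA pair as a random block, the preparation label as a block, separate channels, either dye orientation alone, an intensity trend with a robust prior, and each preparation or 1 RNA pair left out. Analyses used R 4.3.3, limma 3.58.1 and the package data.table, version 1.17.8.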

Results

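Transcript levels were compared between a motile wild type of the unicellular cyanobacterium Synechocystis and a mutant in hfq, the gene for its orthologue of the RNA chaperone Hfq. Total RNA came from exponentially growing liquid cultures. The labels name 2 RNA preparations per strain, 04/07 and 10/07, and do not say what these numbers stand for or whether the preparations came from separate cultures. Every wild-type preparation was hybridised against every hfq preparation, and each of these 4 RNA pairs was hybridised in both dye orientations, which gave 8 two-colour arrays on 1 slide. Each array carried 15208 spots for 8091 probes of 3264 genes, and 3263 genes had values on enough arrays to be tested. Median spot signals ranged from 1149 to 9731 in Cy3 and from 756 to 6892 in Cy5. At least 99.6% of spots on every array were well above background in each channel, and 0 spots were saturated. The number of preparations, 2 per strain, limits the precision. In the fit with no term for the preparation label, p-values of single genes measure the spread between these preparations, which may be technical. With terms for strain and label they measure how far the strain difference varied between labels, with 1 residual degree of freedom. Camera with the preset correlation judges a list by the spread across genes. Its p-values, however small, therefore do not measure the spread between preparations. The arrays name genes by locus tag, without coordinates, so functions are given as background.

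The mutated gene itself, ssr3341, was measured first. Its level was 0.43 ± 0.29 (log2, SE, n = 2 preparations per strain) higher in the RNA labelled hfq, a difference that did not pass the test (limma, adjusted p = 1.00). It was above 0 on 6 of 8 arrays, and its 4 pair ratios lay between 0.17 and 0.77. An insertion can leave a transcript at the probes, and the labels do not say which part of the gene was changed, so this value does not check the strain labels.

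The main question was which transcripts differ when this gene is inactivated, in a study of cell motility. Transcripts of the neighbouring loci slr1667 and slr1668, known to depend on the cAMP receptor protein and tied to motility, differed most between the strains. By the deposited dye labels, slr1667 was 53.5-fold higher in the RNA labelled hfq (log2 5.74 ± 0.34, SE, n = 2 preparations per strain; limma, adjusted p = 0.0115). Likewise slr1668 was 28.6-fold higher in that RNA (log2 4.84 ± 0.35, SE; limma, adjusted p = 0.0165). This direction opposes the study's own published account, in which these transcripts are lowered in the mutant. If the dyes were entered the other way round on all arrays, every sign between the strains given here turns. For that reason the samples are called the RNA labelled hfq and the RNA labelled wt.

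In this fit, with 1 value per preparation and no term for the preparation label, 2 of 3263 genes passed, slr1667 and slr1668; fits with other terms or units of replication called more genes, lower ones included. Both genes were higher in the RNA labelled hfq on 8 of 8 arrays. Within the 10/07 preparations, log2 values were 5.78 for slr1667 and 4.34 for slr1668. Within the 04/07 preparations they were 5.66 and 5.36. Both probes of each gene gave the same sign, with means between 4.72 and 5.94; in a fit per probe 3 of these 4 passed, and 1 of slr1668 did not. With limma, 116 genes had an unadjusted p under 0.05, 70 higher and 46 lower in the RNA labelled hfq. If no gene differed and preparations were independent, about 163 would be expected; the preparations of 1 label deviated alike in both strains, so this number is no measure of how many genes differ. No gene that was lower passed the test in this fit. The 5 lower genes with the smallest p and all 4 pair ratios below 0 were sll1942 at log2 -1.46 ± 0.33, ssl3445 at -1.14 ± 0.26, ssr1256 at -1.17 ± 0.30, sll1825 at -1.18 ± 0.31 and sll1130 at -0.97 ± 0.26 (SE). Their limma adjusted p-values lay between 0.879 and 0.944. With the preparation label as a block all 5 passed over all genes (limma, adjusted p between 0.000354 and 0.00493). Leaving out 1 preparation leaves 1 strain with a lone preparation, so only effect sizes are given here. With each preparation left out in turn, log2 values ran from 5.44 to 6.05 for slr1667 and from 4.45 to 5.22 for slr1668. One array, with wt 04/07 in Cy3 and hfq 10/07 in Cy5, carries growth notes that swap the strains between its channels; its slr1667 log2 ratio was 6.69 under its title, with the sign of all other arrays.

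**Figure D1:**
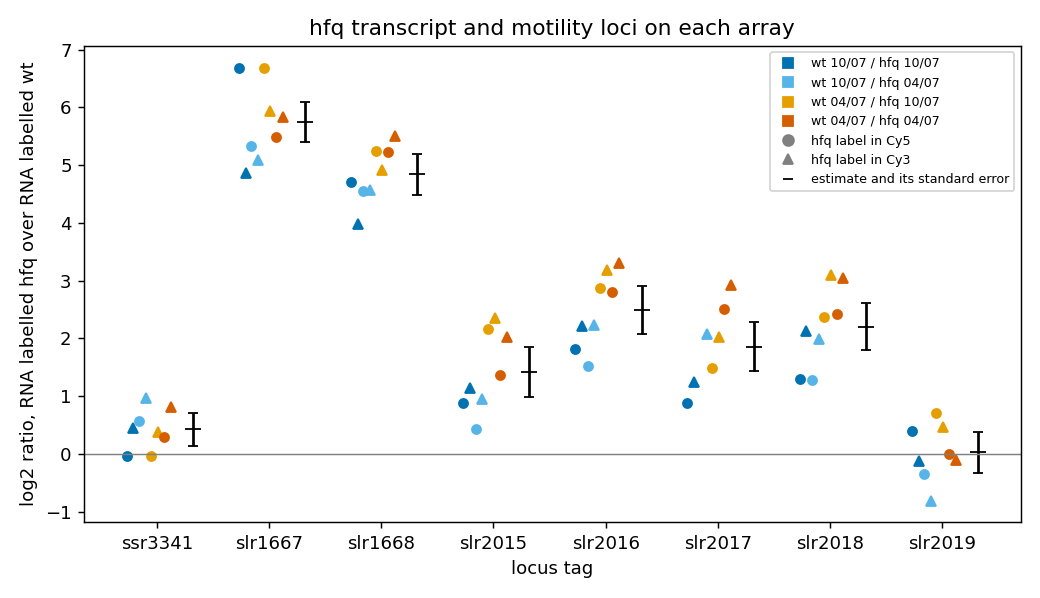
Log2 ratios of the RNA labelled hfq over the RNA labelled wt on each of the 8 arrays for the hfq transcript (ssr3341) and the 7 motility loci; colours mark the RNA pair, circles and triangles the dye orientation, and black bars the estimate with its standard error; slr2017 has values on 7 arrays. The loci slr1667 and slr1668 sit far above 0 on all 8 arrays, at estimates of 5.74 and 4.84, whereas slr2019 lies around 0.

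The list of motility operons held 7 measured loci, slr1667, slr1668 and slr2015 to slr2019, of which slr2015 to slr2017 are known as minor pilin-like genes. All 7 were above 0, with a median log2 of 2.20. In the fit with no term for the preparation label 2 of them passed over all genes, slr1667 and slr1668. Of the others, slr2016 was at 2.49 ± 0.41, slr2018 at 2.20 ± 0.40, slr2017 at 1.86 ± 0.43 and slr2015 at 1.41 ± 0.44 (log2, SE). The probes of slr2015 were far apart, at means of 2.10 and 0.73, and the latter was -0.11 on its lowest array. Adjusted over the list alone in that fit, 6 of 7 members passed. With the preparation label as a block the same 6 passed over all genes, all higher. The exception was slr2019 at 0.03 ± 0.35, whose sign turned with single preparations. The list stood above the other genes by camera (adjusted p = 1.25e-15), but not with an estimated correlation (camera, adjusted p = 0.610, unadjusted p = 0.0587). The estimated correlation within the list was 0.64, against the preset 0.01. That form of the test rests on 2 residual degrees of freedom, and many lists shared its adjusted p of 0.610. The list median was 1.71 within the 10/07 preparations and 2.74 within the 04/07 preparations. The list was drawn partly from published work on this mutant. Its shift, the direction of it and its test results are therefore not independent evidence.

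Pilin genes shared 4 loci with the motility list, slr2015 to slr2018. All 12 measured genes of the pilin list were above 0, with a median log2 of 0.48, at 0.48 within the 10/07 and 0.72 within the 04/07 preparations. In the fit with no term for the preparation label 0 passed over all genes, and 3 passed adjusted over the list alone. With that label as a block 4 passed over all genes, all higher. These 4 were slr2015 to slr2018, and the 3 that passed over the list alone were among them. The 8 pilin genes outside the motility list had log2 values from 0.02 to 0.52, with a median of 0.23. Membership of slr2018 and slr1046 is less sure than that of the others; without slr1046, at 0.02 ± 0.28 and left out after the values were seen, the median of the 11 genes was 0.49, and that of the 7 outside the motility list 0.28. By camera the pilin list stood above the other genes (adjusted p = 8.30e-07), and with an estimated correlation it did not (adjusted p = 0.610). Both tests included the 4 loci shared with the motility list, so they do not show a shift of the other 8 genes. Genes for assembly of the type IV pilus, the surface fibre that drives twitching motility, went the other way: 10 of 11 were below 0, with a median of -0.42. Examples were slr1275 at -0.62 ± 0.31, slr1276 at -0.59 ± 0.29 and slr1274 at -0.58 ± 0.28 (log2, SE), genes of 1 pilus assembly cluster, and the retraction motor gene slr0161 at -0.52 ± 0.27. None passed in this fit, singly or adjusted over the list alone. The list median was -0.22 within the 10/07 and -0.65 within the 04/07 preparations. The list stood below the other genes by camera (adjusted p = 0.00346; adjusted p = 0.610 with an estimated correlation). In the chemotaxis-like clusters 15 of 16 genes were above 0, with a median of 0.27, and sll1292, at 0.79 ± 0.28, had the smallest p. Within the 10/07 and 04/07 preparations that median was 0.11 and 0.36. That list also stood above the other genes (camera, adjusted p = 0.00441, and 0.610 with an estimated correlation). In the fit with no term for the preparation label 0 members passed in either adjustment. With that label as a block 1 passed over all genes, and it was higher.

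Heat shock and chaperone genes formed a further group above 0, with 9 of 12 members and a median log2 of 0.55. The small heat shock protein gene sll1514 was at 1.90 ± 0.35, the chaperonin genes slr2076 and slr2075 were at 1.57 ± 0.28 and 1.52 ± 0.30, and sll0170, a DnaK-type chaperone gene, was at 0.78 ± 0.29 (SE). Of these, sll1514, slr2075 and slr2076 passed adjusted over the list alone in the fit with no term for the preparation label, and 0 passed over all genes. With that label as a block, 5 genes of the list passed over all genes, all higher. The list stood above the other genes by camera (adjusted p = 1.68e-05; adjusted p = 0.610 with an estimated correlation). Its median was 0.57 within the 10/07 and 0.54 within the 04/07 preparations. Genes of nitrogen assimilation were above 0 in 12 of 14 cases, with a median of 0.40, at 0.08 within the 10/07 and 0.50 within the 04/07 preparations. They were led by the nitrate transporter genes sll1451 at 1.12 ± 0.62, sll1450 at 1.06 ± 0.60 and sll1452 at 0.88 ± 0.47, whose pair ratios ran from 0.06 to 0.29 against hfq 10/07 and from 1.37 to 2.17 against hfq 04/07. This list passed by camera (adjusted p = 0.00346), but not with an estimated correlation (adjusted p = 0.610). In the fit with no term for the preparation label 0 of its genes passed in either adjustment. With that label as a block 1 passed over all genes, and it was higher.

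Ribosomal protein and phycobilisome genes lay on the lower side. Of 46 ribosomal protein genes 9 were above 0, and the median was -0.28, with ssl3445 at -1.14 ± 0.26, sll1806 at -0.95 ± 0.30, sll1805 at -0.94 ± 0.28 and ssl3436 at -0.87 ± 0.29 (log2, SE). By camera this list stood below the other genes (adjusted p = 2.78e-09; adjusted p = 0.610 with an estimated correlation). Of 15 genes of the phycobilisome, the light-harvesting antenna, 3 were above 0, and the median was -0.18. The allophycocyanin genes slr1986 and slr2067 were at -0.97 ± 0.32 and -0.92 ± 0.31, the linker genes ssr3383 and slr0335 at -0.75 ± 0.33 and -0.68 ± 0.35. The list passed by camera (adjusted p = 0.00304; adjusted p = 0.610 with an estimated correlation). Its median was -0.0035 within the 10/07 preparations and -0.60 within the 04/07 preparations; for the ribosomal proteins these values were -0.15 and -0.50. In both lists 0 genes passed in the fit with no term for the preparation label, over all genes or adjusted over the list alone. With that label as a block, 8 ribosomal protein and 2 phycobilisome genes passed over all genes, all lower. Of these 8 lists, 4 lost the camera call without wt 04/07 and again without hfq 04/07: type IV pilus assembly, the chemotaxis-like clusters, the phycobilisome and nitrogen assimilation. Without hfq 10/07 the chemotaxis-like clusters and the heat shock genes lost it (for the latter camera, adjusted p = 0.0617).

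The other 13 tested lists did not pass by camera, with adjusted p between 0.0643 and 0.856. Some passed in other fits: chlorophyll biosynthesis with median centring (camera, adjusted p = 0.0473), without wt 10/07 (0.0113) and without hfq 10/07 (0.0207), photosystem I without wt 10/07 (8.19e-05), and high light and photosystem repair without hfq 04/07 (0.0193). Carbon concentration and fixation passed without wt 04/07 (camera, adjusted p = 0.00411) and without hfq 10/07 (0.0287), where the phosphate response (0.00165) and the iron response (0.0418) passed as well. Their median log2 values were 0.22 for the iron response, 0.21 for the hydrogenase, 0.17 for high light and photosystem repair, 0.16 for the phosphate response, 0.14 for cytochrome b6f and electron carriers and 0.12 for sigma factors. They were 0.09 for RNA chaperones and RNases, 0.07 for carbon concentration and fixation, 0.01 for photosystem II, -0.02 for cAMP signalling, -0.06 for the ATP synthase, -0.18 for chlorophyll biosynthesis and -0.24 for photosystem I. For photosystem II and cAMP signalling the mean, at -0.01 and 0.06, had the opposite sign to the median, and camera followed the mean; both medians lay near 0 and turned sign with other processing, to -0.080 for photosystem II with median centring and 0.0079 for cAMP signalling without background correction. In the fit with no term for the preparation label, 0 members of the 13 lists passed over all genes or adjusted over the list alone. Single members with an unadjusted limma p under 0.05 in that fit were the photosystem I gene slr1655 at -0.97 ± 0.37, the principal sigma factor gene slr0653 at -0.67 ± 0.26 and slr1516, a superoxide dismutase gene, at 0.66 ± 0.26. With that label as a block, 5 carbon concentration and fixation genes passed over all genes, 4 higher and 1 lower. So did 1 gene each of photosystem I, sigma factors, cAMP signalling and the phosphate response. The bicarbonate transporter gene slr1512 and its neighbour slr1513 had log2 values of 2.78 ± 1.33 and 1.95 ± 0.90, with slr1512 pair ratios from -0.30 to 5.66. The phycobilisome degradation genes ssl0452 and ssl0453, too few to test as a list, were at -0.26 ± 0.52 and -0.33 ± 0.44, with a median of -0.30.

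The second comparison set the 10/07 preparations against the 04/07 preparations, with strain as a covariate. This fit holds a term for the label that the fit calling 2 genes between strains lacks, so their counts cannot be set side by side. With both terms, the strain difference passed in 176 genes. In this fit 389 genes were higher and 538 lower in 10/07 (limma), and 277 of these 927 differed at least 2-fold, 45 higher and 232 lower. The furthest, named after their values were seen, were the manganese transporter genes sll1598, sll1599 and sll1600. They were lower in 10/07 by 17.3-fold, 17.0-fold and 8.57-fold, at log2 -4.11 ± 0.21, -4.09 ± 0.21 and -3.10 ± 0.21 (SE, n = 2 preparations per label). For sll1598 the difference was -4.49 in the RNA labelled wt and -3.73 in the RNA labelled hfq. Also chosen after their values were seen, slr0374 at 1.87 ± 0.22 and slr0373 at 1.79 ± 0.24 were the furthest above 0. Across genes, the difference in the RNA labelled wt and that in the RNA labelled hfq correlated with r = 0.749 (Spearman 0.712), although genes are not independent replicates. Its standard deviation over genes was 0.579 in wt and 0.652 in hfq. Between strains, also 1 preparation against 1, it was 0.397 within 10/07 and 0.503 within 04/07.

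**Figure D2:**
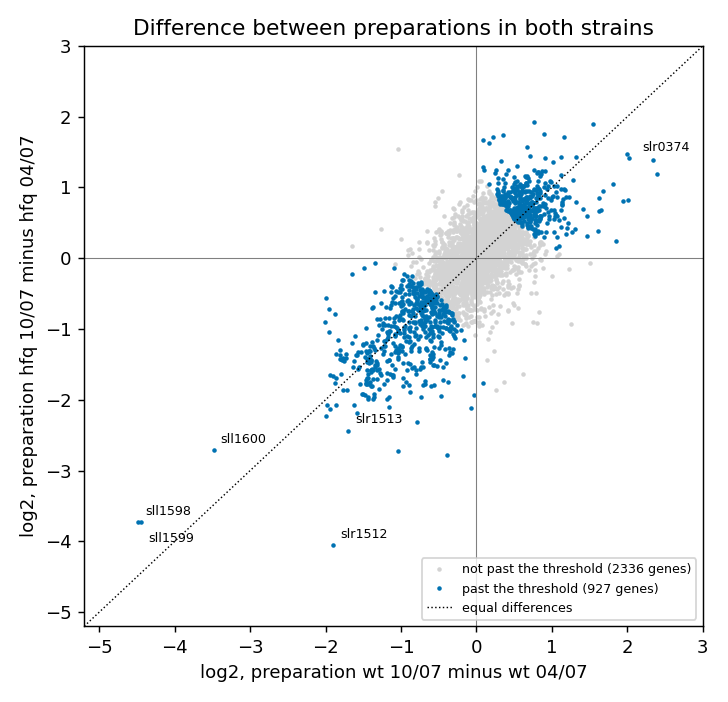
Log2 difference between the 10/07 and 04/07 preparations of the RNA labelled wt (horizontal axis) and of the RNA labelled hfq (vertical axis), 1 point per gene, with the 927 genes past the threshold in blue and a dotted line of equal differences. The points follow the line (r = 0.749), with sll1598, sll1599 and sll1600 at the lower left.

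Among inorganic carbon and phosphate genes, more were lower than higher in the 10/07 preparations; the members named as examples were chosen after their values were seen. Of 20 genes for carbon concentration and fixation, 10 were lower, 0 higher and 10 did not pass, with slr1512 at log2 -2.98 ± 0.32, slr1513 at -2.07 ± 0.21, sll1733 at -1.78 ± 0.19 and sll1732 at -1.71 ± 0.19 (SE). The list median was -0.57 in wt and -0.41 in hfq. Of 14 phosphate response genes, 7 were lower, 1 was higher and 6 did not pass, with slr1248 and slr1249 of a phosphate transporter at -1.72 ± 0.20 and -1.71 ± 0.20. Heat shock and chaperone genes went up in 4 of 12 cases and down in 1, with sll0058 at 0.92 ± 0.20 and slr1204 at 0.84 ± 0.20. These 3 lists passed by camera, with adjusted p of 0.00141, 0.00707 and 0.0217, and did not pass with an estimated correlation (adjusted p = 0.976), which rests on 1 residual degree of freedom. Iron response genes split, with 6 lower and 2 higher: the iron uptake genes slr1295 and slr0513 were at 1.73 ± 0.20 and 1.42 ± 0.21, and sll1404 was at -1.27 ± 0.19. Of 11 photosystem I genes 6 were lower and 1 higher, but the list median of -0.59 turned to 0.23 with median centring of the arrays. Both phycobilisome degradation genes were higher in 10/07, ssl0452 at 1.05 ± 0.21 and ssl0453 at 0.84 ± 0.20. Among the motility loci slr2015, slr2019 and slr1667 were higher in 10/07, at 0.78 ± 0.21, 0.58 ± 0.19 and 0.55 ± 0.19.

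**Figure D3:**
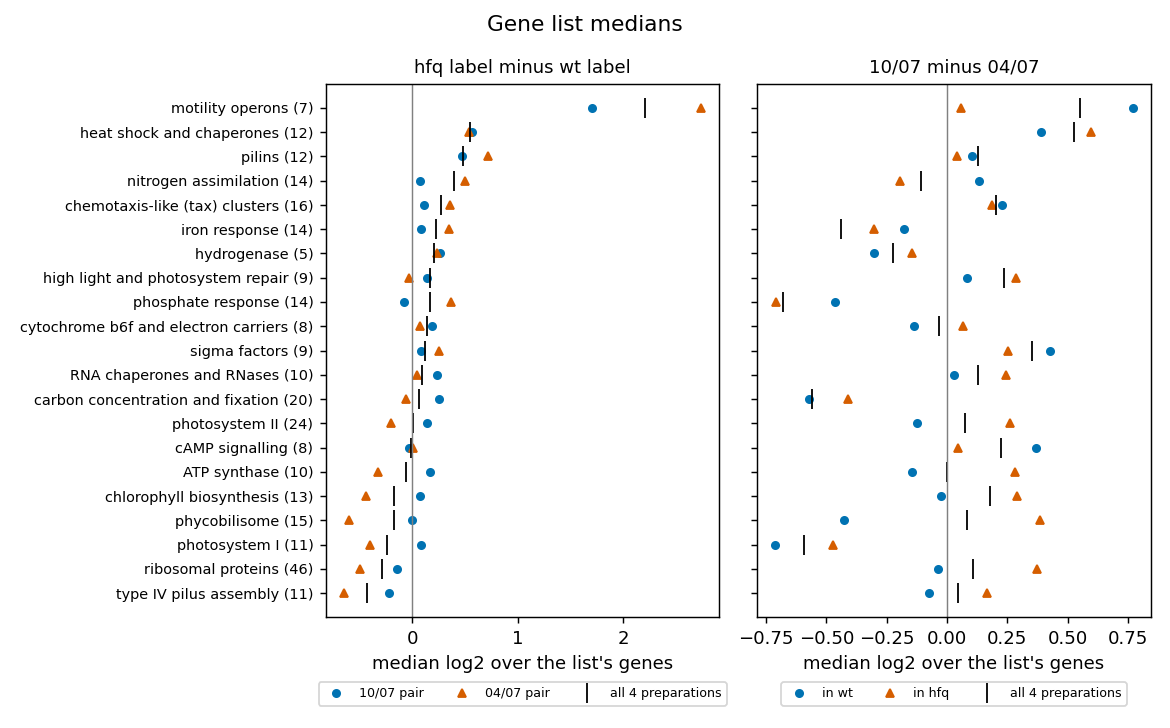
Median log2 over the genes of each tested list, with the number of measured genes in parentheses: left, the RNA labelled hfq minus the RNA labelled wt within the 10/07 pair (circles), the 04/07 pair (triangles) and over all 4 preparations (bars); right, 10/07 minus 04/07 in each strain and over all preparations. The motility operons stand apart on the left at 2.20, and the phosphate response is lowest on the right at -0.68.

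The 4 pair ratios differed in how they related across genes. The ratios of the pairs with matching labels correlated with r = 0.541, and those of the 2 crossed pairs with r = -0.357. Arrays of a dye swap correlated with r between 0.461 and 0.815. The dye effect that the swaps cancel had a standard deviation of 0.223 (log2, Cy5 over Cy3) over genes and exceeded 1 in 11 genes. Among 3202 genes with 2 or more probes, the probes shared a sign in 79.4%, and they did so in all 65 genes with 2 or more probes and at least a 2-fold difference. The 65 genes were selected by the mean of those same probes, so their shared sign was largely fixed in advance and is no independent support. The median standard deviation between probes of a gene was 0.070.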

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

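The tests of explanations for the direction of slr1667 and slr1668 and for the difference between preparations were chosen after the results were seen.

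For slr0906, a photosystem II gene, the array with hfq 04/07 in Cy3 and wt 10/07 in Cy5 gave a log2 ratio of 0.72, and the other 3 arrays of that orientation 0.35 to 0.41. It stood apart by Dixon's criterion, the only such case in 169 tests on the named genes. Chance gives about 1 in 20 per test, so 1 case is no more than chance gives. The arrays of 1 orientation also hold different RNA pairs, so the criterion cannot tell an odd array from a difference between pairs. The pair of wt 10/07 and hfq 04/07 had the highest pair ratio of slr0906, at 1.00 against 0.25 to 0.63. Of 86 named genes compared, a search that did not cover the other genes, 5 had a difference in sign: both arrays of the 10/07 pair had the opposite sign to both arrays of the 04/07 pair, a difference that was not tested. Mean log2 ratios were 0.10 and -0.52 for slr0737, 0.16 and -0.76 for sll1323, 0.11 and -0.64 for sll1324, 0.070 and -0.91 for slr0506, and -0.59 and 0.28 for sll0679.

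The direction of slr1667 and slr1668, higher in the RNA labelled hfq, goes against the study's account. Dyes entered the other way round on only some arrays would leave arrays of opposite sign, and both genes were higher in that RNA on 8 of 8 arrays. A single faulty probe is argued against as well, since the lowest mean log2 of the 4 probes was 4.72. Dyes entered the other way round on all arrays, or the strains exchanged in all 4 preparations, could account for it, and nothing measured here decides this: ssr3341, at 0.43, did not pass the test, and where its probes lie relative to the mutation is not given in the sources used here. A real rise of both transcripts in the mutant cannot be told apart from such a reversal.

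The 10/07 and 04/07 preparations differed in a like manner in both strains. An effect of array position on the Cy5 to Cy3 ratio would change sign with the dyes, but across genes the difference correlated between dye orientations with r of at least 0.951 in each strain. Noise that is independent between arrays would give no correlation between strains from arrays of opposite orientation, which share no array, and across genes r was at least 0.736. Handling or labelling shared by preparations of 1 label may have produced the correlation of 0.749 between strains, and so could a shared growth state. These cannot be told apart, because the labels do not say what 04/07 and 10/07 stand for.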

How the results depend on the processing

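Alternatives were planned, except values within a preparation label, the comparison of preparations by dye orientation, list tests on it, list medians under other scalings and pilins without the motility loci or slr1046, which were added after seeing the data. Both slr1667 (log2 5.43 to 6.05) and slr1668 (4.45 to 5.22) passed in every other fit on gene values; per probe, 3 of their 4 probes passed. The 2 genes past the threshold became 39 with 4 pair ratios and 699 with 8 arrays taken as independent, 138 with the RNA pair as a random block and 289 with separate channels. The first and second of these count shared RNA as replicates. The random block still takes RNA pairs that share preparations as independent, and the separate channels all come from the same 4 preparations. With the preparation label as a replicate block the count was 176, 119 higher and 57 lower; same-label deviations correlated with r = 0.749, but with 2 pairs and no explanation in the labels the numbers are not established as pairing. For ssr3341 the 8 arrays taken as independent gave 0.43 past the threshold (limma, adjusted p = 0.0207, against 0.242 with the block). Leaving out 1 preparation, where the lone one is assumed to vary like the others, gave 2 to 16 genes (6 without wt 10/07, 16 without hfq 04/07), ssr3341 at 0.19 to 0.66, and 5 to 10 lists by camera against 8. With an estimated correlation 0 lists stood apart from the other genes, and by fry, which compares a list with no other genes, 0 passed. The former rests on 2 residual degrees of freedom, so it says little about whether lists differ. Its smallest unadjusted p-values were 0.0305 for pilins and 0.0587 for motility operons (camera), and adjustment gave many lists the same 0.610. Median centring moved the dye effect to 0.244.

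Signs turned for genes not past the threshold. With wt in Cy3 only, values were 0.10 for ssr0390, -0.060 for slr1643, 0.0013 for sll0679, -0.045 for sll1221 and -0.031 for sll1220, and with hfq in Cy3 only -0.14 for slr2019. Leaving out 1 preparation gave -0.32 to 0.37 for slr2019 (-0.22 without wt 04/07), -0.51 to 0.032 for slr0737, -0.037 to 0.40 for sll2012, -0.44 to 0.018 for sll0679, -0.15 to 0.88 for sll1405, -0.15 to 1.12 for sll1404, -0.68 to 0.14 for sll1323, -0.69 to 0.23 for sll1324, -0.95 to 0.10 for slr0056, -0.86 to 0.10 for slr0506, -0.071 to 0.63 for sll0683, -0.82 to 0.26 for sll0646 and -1.34 to 0.22 for slr0327; the cause was not tested. Over the 86 named genes besides ssr3341, 1450 values kept direction and side of the threshold, 163 passed it newly and 21, those above, reversed. The comparison of preparations called 713 to 1045 genes against 927, of which 784 kept call and sign with median centring, 795 with Agilent's ratios, and 748 and 708 in the single orientations. The filter on dim probes removed 0 probes and tests nothing, a slide block was not run with 1 slide, and leaving out a preparation leaves that comparison no residual degree of freedom. Signal over background limits little, since at least 99.6% of spots were well above it.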

Other observations

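Further loci, some of them in runs of consecutive tags, stood above 0 in the RNA labelled hfq and were chosen after their values were seen. None passed in the fit with no term for the preparation label (limma, adjusted p of at least 0.402), which does not show that they do not differ. With that label as a block, every locus named in this paragraph but slr0152 passed over all genes (limma, adjusted p of at most 0.00816). The short loci ssr2848 and ssr2787 were at log2 3.43 ± 0.52 and 2.55 ± 0.40, and sll1543 was at 2.45 ± 0.40 (SE, n = 2 preparations per strain). Pair ratios ran from 2.58 to 4.76 for ssr2848, from 1.98 to 3.24 for ssr2787 and from 1.68 to 3.68 for sll1543. The locus with the smallest p after slr1667 and slr1668 was slr0442, at 1.78 ± 0.26 with pair ratios from 1.63 to 1.94. The run slr0868 to slr0871 had values of 1.09, 1.83, 2.18 and 1.64, and sll1239 to sll1241 of 1.61, 1.11 and 1.21. In the cluster slr0144 to slr0151, tied to photosystem II assembly, values were 1.11, 1.15, 0.96, 1.05, 1.03, 1.04, 1.06 and 0.95, whereas the next locus, slr0152, was at 0.02 ± 0.28.

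The bicarbonate and nitrate transporter genes had pair ratios that differed widely between preparations. For slr1512 the pair ratios were 5.66 and 3.95 against hfq 04/07 and 1.80 and -0.30 against hfq 10/07. For the nitrate transporter gene sll1451 they were 2.07 and 2.11 against hfq 04/07 and 0.20 and 0.11 against hfq 10/07. The manganese transporter gene sll1598 had ratios of 1.02 and 0.26 in the pairs with matching labels and of 4.96 and -3.26 in the crossed pairs. Each of these values is from 1 RNA pair, with no test.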
